A study of Mus musculus with 12 samples.

How the data were processed

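The 12 libraries were made from sorted splenic cDC and pDC of WT, het and KO mice, with 2 biological replicates per group per the labels. Per the submitters' processing notes, reads of 100 bases, sequenced from a single end, were aligned to mm10 with Subread 1.4.6 and counted per gene with featureCounts. The deposited values are raw read counts per gene, with no normalisation, beside a column with the gene length in bases as the counting tool gives it. The strand setting of the counting is not stated, so genes that overlap on opposite strands may hold each other's reads, and genes with near-identical copies (Ly6, tissue kallikrein, H2 and Ly49 families) share reads that the counting may have placed in the wrong copy.

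Each table had 27179 genes identified by GeneID. Names were found for 25275 of them in a RefSeq annotation of GRCm38 and for 18 in GENCODE, and the 1886 without a name held 0.52% to 0.75% of the counts of a library. Total counts ran from 12745361 to 17665821. For genes with fewer than 4 counts over the libraries of a group, the fold is given as a floor computed from 3 counts, where the group had none, or as a ratio with an exact 95% interval for counting error.

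Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10), libraries were scaled by TMM (factors 0.953 to 1.063), and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted to all 12 libraries. It had 6 residual degrees of freedom and a biological coefficient of variation of 6.13%. The comparisons were KO against WT, het against WT and KO against het within each cell type, WT pDC against WT cDC, and the KO effect in cDC against that in pDC. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all 13600 genes tested, in 2-sided tests. The SE of a log2 fold change was taken as its size over the square root of the F statistic. CPM are TMM-scaled.

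Gene groups came from 32 lists of cell type markers, gene families and pathways, fixed with the models, comparisons and alternatives before the data were examined. For each list the members called over all genes were counted, and again with the adjustment made over the list alone. The list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. It was also tested with fry, a self-contained test of whether members shift together up or down. List p values were adjusted over the lists of a comparison. Lists share members, so they are not independent. Identity lists of genes that differed by log2 2 or more between cDC and pDC were taken from the het libraries of these samples.

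Genes were named by a rule fixed with the lists. Spi1 came first in every library. Then came the genes with the largest change, 10 per direction for KO against WT and 5 otherwise, among called genes with a mean of at least 5 CPM in 1 of the compared groups and with both libraries of a group above both of the other. Unnamed gene models, immunoglobulin and T cell receptor segments and sex-linked genes were left out. From each list came up to 4 called members with the smallest adjusted p, and in every comparison Spi1, Zfp366, Irf8, Irf4, Batf3, Id2, Tcf4, Spib, Csf1r and Flt3. For length, some genes that the rule names and some results of lists in single comparisons are left out of the report. Levels of a named gene in a group outside the comparison are given for scale.

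The methods were tested on simulated data with 200 changed genes among 13364, built on the fitted dispersions. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery was not tested below that level. The model recovered 88.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 7% false among those called. For the difference between the KO effects it recovered 67.2%, 85.1% and 98.5%, with 4% false. Camera gave p below 0.05 for 0.5% of 200 lists of random genes without a change. Their counts were drawn independently for each gene, so this does not show how camera performs on lists of correlated genes. With a simulated length trend, over 13393 genes, 94.1% of calls were false, and 11.1% once length offsets were applied. The data had far more genes called, 8320 for KO against WT in cDC and 7990 in pDC, and a length trend in the KO libraries. The rates simulated without that trend therefore do not describe the KO calls.

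The alternatives tried were RLE size factors, the DESeq2 1.42.0 Wald test, limma voom, no filter and a stricter filter (above 1 CPM in 2 libraries), a fit of the compared groups only, a replicate block, a fit without robust dispersion, each library left out in turn, and removal of immunoglobulin, T cell receptor, mitochondrial and sex-linked genes. Added after the data were seen were offsets that take out each library's loess trend (span 0.5) of log2 CPM on log2 gene length, a test against a 1.5-fold change, and fits without the het libraries. Correlation expected from shared controls was taken from 20 simulated draws without effects. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.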

Results

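RNA was sequenced from dendritic cells (DC) sorted from the spleens of mice in which Cre recombinase, driven by the Itgax promoter, deletes floxed Spi1, the gene of the transcription factor PU.1. Conventional DC (cDC, sorted as CD11c+ MHC II+ NK1.1- CD19- Siglec-H-) and plasmacytoid DC (pDC, sorted as CD11c+ Bst2+ Siglec-H+ NK1.1- CD19-) were each taken from wild-type (WT), heterozygous (het) and knockout (KO) mice. Each of the 6 groups had 2 biological replicates, which gave 12 libraries of 12745361 to 17665821 gene-assigned counts. A model fitted to all 12 libraries tested 13600 genes. Log2 fold changes are printed ± their SE, with n = 2 libraries in every group, and expression as mean CPM, counts scaled to a library of 1e+06. A gene is said to rise, fall or change only where the model called it at an adjusted p below 0.05.

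Spi1 (GeneID 20375, chromosome 2, 91082374 to 91115759 on GRCm38) was read in every library. In cDC its counts were 9353 and 7723 in WT, 8358 and 10423 in het, and 6755 and 6058 in KO. In pDC they were 1875 and 1948 in WT, 2470 and 2190 in het, and 1273 and 1300 in KO. The mean in cDC was 562.6 ± 34.9 CPM (SD, n = 2) in WT and 405.4 ± 20.8 in KO, a fall of log2 -0.47 ± 0.07 (adjusted p = 2.82e-05). In pDC the mean was 118.2 ± 14.4 CPM in WT and 93.4 ± 2.52 in KO, a fall of log2 -0.34 ± 0.08 (adjusted p = 0.0014). Counts over the whole gene include exons outside the deleted part, so these values do not measure how complete the deletion was. In het cells the mean was 660.9 ± 6.83 CPM in cDC and 143.4 ± 6.42 in pDC, both above WT. The het rise in cDC (log2 0.23 ± 0.07, adjusted p = 0.0196) was no longer called without cDC WT replicate 2 (0.16), cDC het replicate 1 (0.23) or cDC het replicate 2 (0.20). That in pDC (0.28 ± 0.08, adjusted p = 0.0140) was no longer called without pDC WT replicate 1 (0.18) or pDC het replicate 2 (0.25).

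Mybpc3 (GeneID 17868, chromosome 2, 91118114 to 91136516), which encodes a heart muscle protein and is the gene next to Spi1, made the largest change of any gene in KO cells. In cDC it went from 0.735 CPM in WT through 46.2 in het to 2845 in KO, a KO rise of log2 11.92 ± 0.14 (adjusted p = 1.12e-19). In pDC it went from 2.49 through 8.73 to 681 CPM, a KO rise of log2 8.09 ± 0.12 (adjusted p = 4.65e-18).

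**Figure D1:**
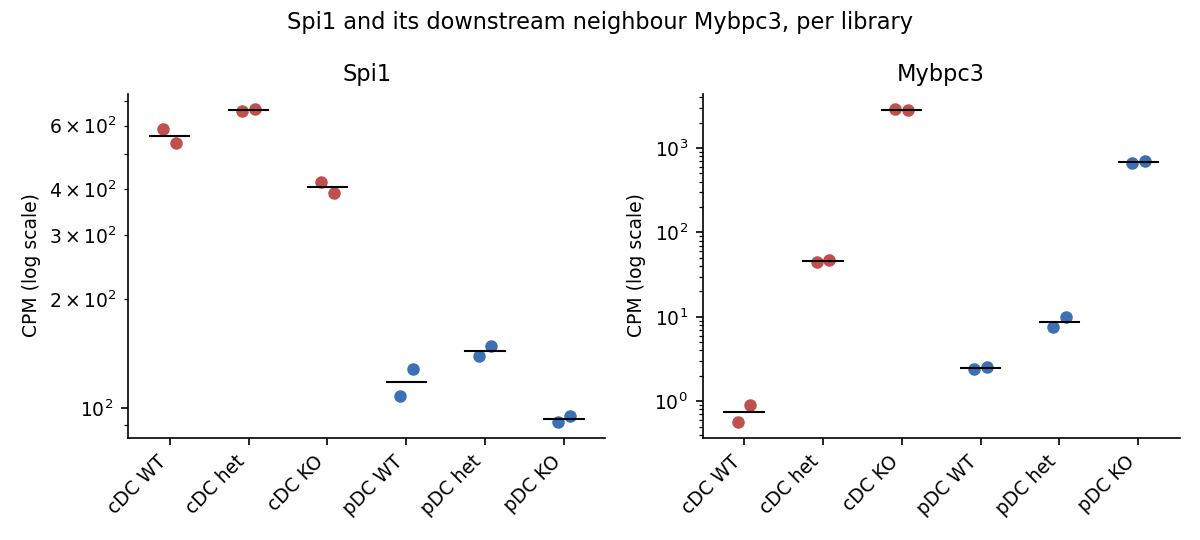
CPM (log axis) of Spi1 and of its neighbour Mybpc3 in each of the 12 libraries, with 2 dots per group and a line at the group mean. Spi1 stays between 91.6 and 148 CPM in pDC and between 391 and 666 in cDC, whereas Mybpc3 climbs from 0.735 to 2845 CPM in cDC.

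Cell type and genotype separated the libraries. The leading principal component of 10274 genes held 70.8% of the variance and divided cDC from pDC, and the next held 16.8% and set the 4 KO libraries apart from the other 8. Replicates correlated at 0.9898 to 0.9971, while all 6 pairs differed by more than sampling noise, with a chi-square per degree of freedom of 2.01 to 11.4.

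WT pDC were compared with WT cDC. Of the 9549 genes that differed, 4831 were higher in pDC and 4718 in cDC. Tcf4, the E protein that directs pDC fate, was higher in pDC by log2 3.81 ± 0.07, Spib by 3.28 ± 0.07 and Irf8 by 2.27 ± 0.06. Siglech stood at 15.6 CPM in cDC and 4193 in pDC, a difference of 8.07 ± 0.10. Ly6d (8.51 ± 0.11), Pacsin1 (6.16 ± 0.09) and Runx2 (4.47 ± 0.07) were higher in pDC, as were Dntt (9.53 ± 0.22), Il7r (4.45 ± 0.09), Notch1 (4.39 ± 0.12) and Myb (3.51 ± 0.10), which are known from early lymphoid cells. Zfp366, which encodes DC-SCRIPT, was lower in pDC by log2 -6.03 ± 0.16, beside Batf3 (-4.81 ± 0.19), Id2 (-4.64 ± 0.26), Spi1 (-2.25 ± 0.08), Csf1r (-2.61 ± 0.31) and Flt3 (-0.39 ± 0.06), and Irf4 did not differ (-0.09 ± 0.12). Naaa (-4.79 ± 0.08), Gcsam (-5.70 ± 0.14), Itgam (-4.59 ± 0.09), Lyz2 (-3.99 ± 0.08), Fzd1 (-6.88 ± 0.17) and Slc8a2 (-7.40 ± 0.21) were also lower in pDC. Among genes with few counts in a cell type, Olfr164 was at least 317-fold, Slc22a12 at least 139-fold, Lgr5 at least 127-fold and Gfra3 at least 85.3-fold higher in pDC, and Sel1l3 was at least 60.5-fold lower. Such floors, and the counting intervals given below, cover counting error only, because the reads carry no molecular identifiers.

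By list, all 24 pDC markers were higher in pDC, and all 24 with the adjustment made over the list alone. Of 19 cDC1 markers 16 were lower and 2 higher (list alone 16 and 2), and of 20 cDC2 markers 13 were lower and 5 higher (list alone 13 and 5). All 15 MHC class II presentation genes were lower in pDC, with H2-Eb1 at -2.36 ± 0.06, H2-Ab1 at -1.72 ± 0.07, H2-Ob at -3.21 ± 0.07 and Ciita at -1.99 ± 0.06 (list alone 15). All 28 cell cycle genes were lower (list alone 28), as were 16 of 17 NK cell markers (list alone 16). The early lymphoid list had 8 of 12 genes higher and 3 lower in pDC (list alone 8 and 3). The cDC were sorted as MHC II+ and Siglec-H-, and the pDC as Bst2+ and Siglec-H+ without an MHC II gate. The sort itself therefore favours the directions seen for MHC class II genes, Siglech and Bst2.

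KO cDC were compared with WT cDC to ask which genes change with loss of PU.1 in a cell type that holds it at a high level. The labels give no day of sorting or preparation. Neither this comparison nor that in pDC therefore separates PU.1 loss from the handling of the cells. The model called 8320 genes, of which 4145 rose and 4175 fell, and 1409 rose and 1260 fell by 2-fold or more. Zfp366 (GeneID 238803, chromosome 13, 99184823 to 99247032), a cDC-restricted regulator, dropped from 283 to 37.6 CPM, log2 -2.91 ± 0.12 (adjusted p = 6.11e-10). Irf8, which cDC1 require, fell by 0.69 ± 0.06 (adjusted p = 2.21e-08), Irf4 by 0.73 ± 0.13 (0.000405), Batf3 by 0.54 ± 0.13 (0.00208) and the growth factor receptor gene Flt3 by 0.60 ± 0.06 (5.79e-08). The pDC regulators moved the other way, with Spib rising from 144 to 422 CPM (1.55 ± 0.06, adjusted p = 1.79e-12) and Tcf4 from 95.2 to 219 CPM (1.20 ± 0.07, adjusted p = 6.55e-11). Neither Csf1r (0.76 ± 0.29, adjusted p = 0.0598) nor Id2 (0.10 ± 0.21, adjusted p = 0.701) was called.

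Beside Mybpc3, the largest rises in KO cDC were those of Gzmc, Plcb1, Ly6k, Ly6a2, Sdc1, Cbln1, Gpr15, Htra3 and Podnl1. Gzmc, a granzyme gene without a count in WT cDC, rose at least 155-fold. Plcb1 rose 530-fold (95% counting interval 94.8 to 20980) from 1 count in WT, Ly6k 163-fold (28.9 to 6475) and Cbln1 71.3-fold (24.1 to 348). Ly6a2 rose by log2 6.90 ± 0.38, the plasma cell gene Sdc1 by 6.31 ± 0.28, Gpr15 by 5.99 ± 0.43, Htra3 by 5.71 ± 0.35 and Podnl1 by 5.61 ± 0.56. The largest falls were in Cdhr3, Cd207, Slc8a2, Adgrf5, Frmd5, Ryr3, Pcdh1, Dmrtb1, Gpr82 and Dnajc22. Cd207, which encodes langerin, went from 302 counts to 1, a 315-fold fall (56.1 to 12480), Cdhr3 fell 368-fold (65.7 to 14580) and Adgrf5 131-fold (36.0 to 1091). Slc8a2, a sodium-calcium exchanger gene, went from 73.8 to 0.38 CPM (-7.57 ± 0.22), followed by Frmd5 at -5.66 ± 0.25, Ryr3 at -5.58 ± 0.23, Pcdh1 at -5.53 ± 0.27, Dmrtb1 at -5.50 ± 0.48, Gpr82 at -5.40 ± 0.27 and Dnajc22 at -5.37 ± 0.45.

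Genes of the cDC1 subset, which cross-presents antigen, fell as a group in KO cDC, 18 of 19 (list alone 18) with none risen. Clec9a went from 289 to 89.2 CPM (-1.70 ± 0.06), Tlr11 from 248 to 36.7 (-2.76 ± 0.11), Naaa from 1060 to 278 (-1.93 ± 0.07) and Ppt1 from 1741 to 635 (-1.46 ± 0.07). The list test (camera, adjusted p = 8.98e-17) gave an adjusted p = 0.0594 with an estimated correlation. Among cDC2 markers 10 of 20 fell and 7 rose (list alone 10 and 8; camera adjusted p = 0.0081, and adjusted p = 0.102 with an estimated correlation). Cd4 fell from 375 to 16.2 CPM (-4.53 ± 0.14), and the changes of Clec4a4, Esam and Sirpa were -3.48 ± 0.14, -2.37 ± 0.13 and -0.96 ± 0.05. Genes shared by both cDC subsets fell in 18 of 20 cases (list alone 18; adjusted p = 1.13e-10, and 0.0359 with an estimated correlation), among them Relb (-1.13 ± 0.08), Mycl (-1.12 ± 0.06) and Bcl6 (-1.06 ± 0.07). That list also holds Spi1 itself and the cDC1 marker Batf3.

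The pDC markers rose in KO cDC in 16 of 24 cases and fell in 3 (list alone 16 and 3; adjusted p = 5.51e-13, and 0.0348 with an estimated correlation). Ly6d (GeneID 17068, chromosome 15, 74762056 to 74763567) went from 4.0 to 104 CPM (4.71 ± 0.11), Ly6c2 from 22.1 to 405 (4.20 ± 0.09), Sell from 52.8 to 340 (2.69 ± 0.07) and Runx2 from 53.0 to 222 (2.06 ± 0.06). These levels stayed below those of WT pDC, where Ly6d stood at 1455 and Sell at 1573 CPM. The broader identity lists, chosen from the het libraries of these samples, moved alike. Of 1341 genes higher in cDC by log2 2 or more, 661 fell and 385 rose (list alone 670 and 392; adjusted p = 2.26e-06, and 0.13 with an estimated correlation). Of 767 genes higher in pDC, 322 rose and 78 fell (list alone 314 and 72; adjusted p = 7.28e-09, and 0.0145 with an estimated correlation).

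Among DC transcription factors 17 of 31 fell and 8 rose (list alone 17 and 8), and of 9 IRF family genes 7 fell (list alone 7), neither group being called by camera (adjusted p = 0.147 and 0.135). The ETS family, to which PU.1 belongs, had 8 of 17 genes fallen, such as Etv3 (-1.84 ± 0.06) and Ehf (-1.96 ± 0.13), and 5 risen, such as Ets1 at 1.34 ± 0.08 (list alone 8 and 5; adjusted p = 0.63). Platelet genes had 2 of 4 risen in KO cDC (list alone 3; adjusted p = 0.00343, and 0.111 with an estimated correlation). MHC class I genes (8 of 17 risen, 4 fallen; list alone 8 and 4; adjusted p = 0.884) and cytokine receptor genes (6 of 26 risen, 13 fallen; list alone 7 and 13; adjusted p = 0.171) were not called as groups in KO cDC. Nor were basophil and mast cell markers (1 of 4 risen, 2 fallen; list alone 1 and 2; adjusted p = 0.452) and sex-linked genes (1 of 4 risen, 2 fallen; list alone 1 and 3; adjusted p = 0.803). Textbook myeloid targets of PU.1 split into 12 of 32 fallen and 10 risen (list alone 12 and 10; adjusted p = 0.147), with Il1b at -3.30 ± 0.08, Ncf4 at -0.80 ± 0.07 and Fcgr1 at 1.78 ± 0.13.

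Antigen presentation by MHC class II lost expression in 9 of 15 genes and gained it in 2 (list alone 9 and 2; adjusted p = 0.00998, and adjusted p = 0.359 with an estimated correlation). The class II transactivator gene Ciita fell by 1.22 ± 0.06, Marchf1 by 1.4 ± 0.07 and H2-Ob by 1.00 ± 0.07, while Lgmn rose by 0.88 ± 0.08. Co-stimulation and maturation genes fell in 14 of 18 cases and rose in 4 (list alone 14 and 4; adjusted p = 0.000239, and 0.195 with an estimated correlation). Il12b was at -4.28 ± 0.32, Cd274 at -1.78 ± 0.08 and Icosl at -1.03 ± 0.08. Pattern recognition genes fell in 20 of 32 cases and rose in 9 (list alone 21 and 9; adjusted p = 0.000112, and 0.0602 with an estimated correlation), among them Nlrp3 (-2.12 ± 0.08), Tlr5 (-2.05 ± 0.12) and Nod1 (-1.59 ± 0.07). Interferon-stimulated genes fell in 11 of 25 cases, led by Oas2 at -3.20 ± 0.20, and only Bst2 rose, by 1.74 ± 0.09 (list alone 11 and 1; adjusted p = 0.171). This list also fell in het cDC. Immediate-early and dissociation genes, which also respond to tissue handling, fell in 20 of 23 cases (list alone 21; adjusted p = 5.51e-13, and 0.0359 with an estimated correlation). Examples were Dusp1 (-2.44 ± 0.07), Fos (-2.31 ± 0.08), Nfkbiz (-1.95 ± 0.09) and Dusp2 (-1.89 ± 0.08).

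Cell cycle genes rose in 24 of 28 cases in KO cDC (list alone 26), including Cdc20 (1.48 ± 0.10), Birc5 (1.38 ± 0.11), Aurkb (1.24 ± 0.09) and Mcm7 (0.93 ± 0.06). Their camera test (adjusted p = 2.91e-08) gave an adjusted p = 0.285 with an estimated correlation. Of 20 chemokine receptor and migration genes 11 rose and 5 fell (list alone 11 and 6; adjusted p = 0.00417, and 0.0602 with an estimated correlation). Cxcr4 was at 2.20 ± 0.08, S1pr4 at 1.98 ± 0.12 and Itgb7 at 1.38 ± 0.08. The early lymphoid list, which shares Il7r with the innate lymphoid list, had 8 of 12 genes risen and 2 fallen (list alone 8 and 2; adjusted p = 0.00343, and 0.0681 with an estimated correlation). Notch1 was at 2.09 ± 0.12, Lax1 at 2.32 ± 0.26 and Sox4 at 1.21 ± 0.10. Of 18 apoptosis regulators 6 rose and 6 fell (list alone 6 and 6), Mcl1 falling by 0.98 ± 0.06.

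Markers of other cell types rose in KO cDC as well. Those of NK cells, T cells, innate lymphoid cells, monocytes, neutrophils and red cells also rose in het cDC, so their rise was not particular to KO. NK cell markers rose in 15 of 17 cases and fell in 2 (list alone 15 and 2; adjusted p = 1.26e-07, and 0.0602 with an estimated correlation). Ncr1 was at 3.56 ± 0.16, Txk at 3.52 ± 0.27 and Nkg7 at 2.87 ± 0.15. T cell markers rose in 15 of 17 cases and fell in 1 (list alone 15 and 1; adjusted p = 2.46e-05, and 0.0678 with an estimated correlation). Cd6 was at 2.62 ± 0.17 and Thy1 at 2.21 ± 0.21. Innate lymphoid genes rose in 7 of 10 and fell in 2 (list alone 7 and 2; adjusted p = 8.23e-05, and 0.0359 with an estimated correlation). Tox was at 4.66 ± 0.32, Il2ra at 2.63 ± 0.21 and Il7r at 2.48 ± 0.09. Macrophage markers rose in 13 of 17 (list alone 13; adjusted p = 4.76e-05, and 0.359 with an estimated correlation). C1qb was at 2.58 ± 0.27, Cd163 at 2.33 ± 0.12 and Apoe at 1.69 ± 0.10. Monocyte markers, which share Ly6c2 with the pDC list, rose in 10 of 16 and fell in 2 (list alone 11 and 2; adjusted p = 2.16e-05, and 0.0359 with an estimated correlation). Fn1 was at 1.87 ± 0.12 and Plac8 at 1.17 ± 0.08. Plasma cell genes rose in 5 of 8 (list alone 5; adjusted p = 0.0211, and 0.102 with an estimated correlation), including Jchain at 3.79 ± 0.39 and Xbp1 at 0.58 ± 0.07. Neutrophil granule genes rose in 10 of 14 and fell in 1 (list alone 10 and 1; adjusted p = 0.367), and red cell genes rose in 7 of 8 (list alone 7; adjusted p = 0.00788, and 0.383 with an estimated correlation). B cell markers were mixed, with 6 of 15 fallen, such as Ms4a1 (-2.97 ± 0.14) and Cr2 (-3.16 ± 0.29), and 4 risen (list alone 7 and 4; adjusted p = 0.715).

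**Figure D2:**
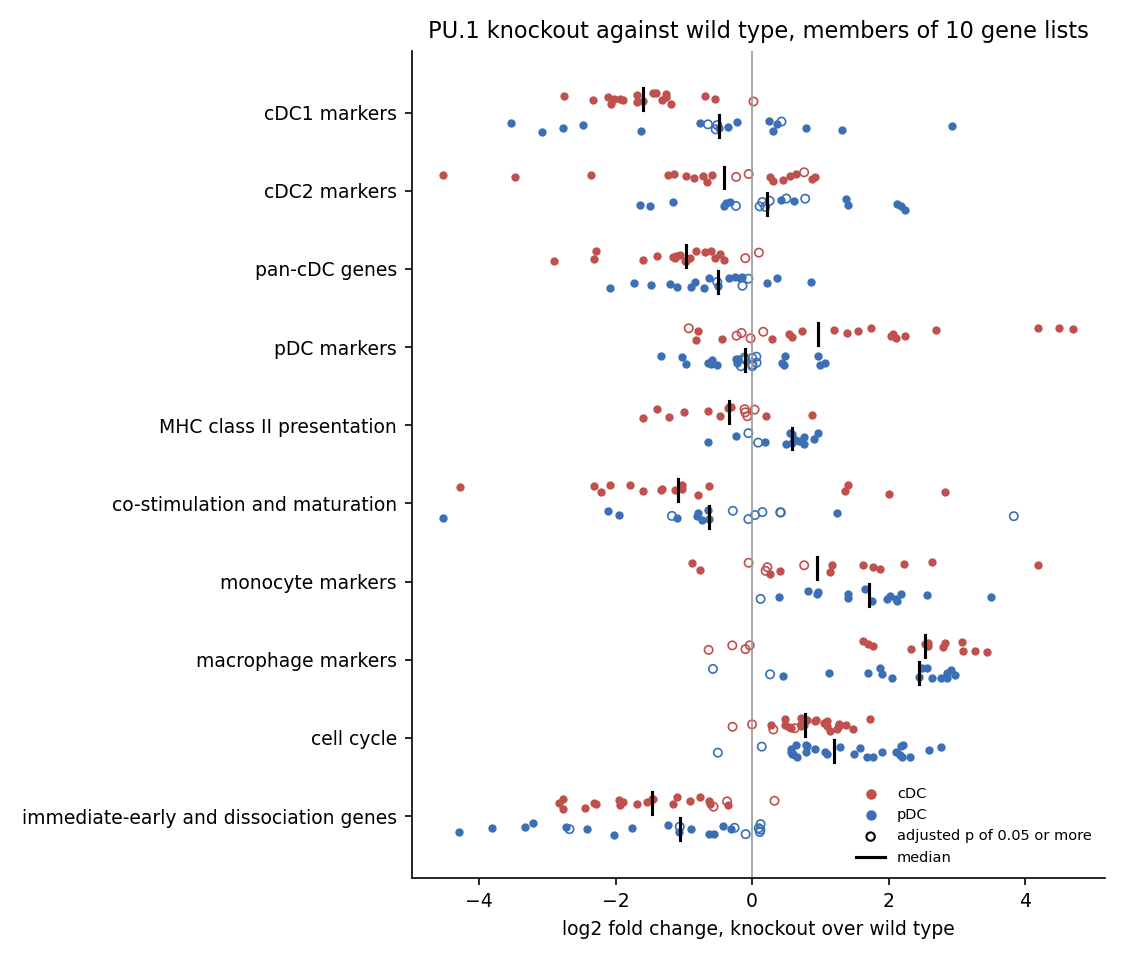
Log2 fold change, KO against WT, of each member of 10 gene lists in cDC (red) and pDC (blue); each dot is a gene, filled dots were called, and black bars mark medians. The cDC1 markers lie below 0 in cDC, with 18 of 19 fallen, and the cell cycle genes lie above 0 in both cell types, with 24 and 26 of 28 risen.

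KO pDC were compared with WT pDC to ask what PU.1 does in a cell type that transcribes its gene at a lower level. The model called 7990 genes, 4110 risen and 3880 fallen, and 893 rose and 1240 fell by 2-fold or more. Among the regulators followed in every comparison, Tcf4 was not called (0.07 ± 0.06, adjusted p = 0.38), Spib rose by 0.43 ± 0.06 (adjusted p = 9.09e-06) and Irf8 fell from 4427 to 3465 CPM (-0.35 ± 0.06, adjusted p = 5.71e-05). Zfp366 fell from 4.3 to 1.0 CPM (-2.08 ± 0.37, adjusted p = 0.000333). The receptor gene Csf1r rose from 101 to 440 CPM (2.13 ± 0.31, adjusted p = 0.00108), a call that was lost when only the compared groups were fitted. Flt3 (-0.17 ± 0.06, adjusted p = 0.0133) was no longer called without pDC WT replicate 2 (-0.15) or pDC KO replicate 1 (-0.13), and Batf3 was not called (-0.51 ± 0.35, adjusted p = 0.231). Id2 rose by 0.86 ± 0.26 (adjusted p = 0.0258), but was not called without pDC WT replicate 1 (0.71), pDC WT replicate 2 (1.03) or pDC KO replicate 1 (0.44). The fall of Irf4 (-0.33 ± 0.13, adjusted p = 0.0418) was lost on leaving out any cDC library, pDC WT replicate 2 or either pDC KO library, and was -0.11 without pDC WT replicate 2.

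After Mybpc3, the largest rises in KO pDC were in Plcb1, at 169-fold (57.5 to 824), and in Gdpd3 (GeneID 68616, chromosome 7, 126766414 to 126775645), a phospholipase gene that went from 1.4 to 95.8 CPM (6.11 ± 0.13). Ly6a2 rose by 5.53 ± 0.30, Apoc1 by 5.01 ± 0.24, Lrrc4c by 4.69 ± 0.31, Ccl24 by 4.44 ± 0.36, Fabp4 by 4.43 ± 0.36, Hp by 4.37 ± 0.25 and Ube2ql1 by 4.06 ± 0.27. The largest falls included the AP-1 genes Fosb (98.6 to 5.0 CPM, -4.30 ± 0.17), Jun (728 to 51.9 CPM, -3.81 ± 0.17) and Fos (277 to 27.5 CPM, -3.33 ± 0.09), all on the immediate-early and dissociation list. They also included Myo1h (-4.18 ± 0.42), the olfactory receptor gene Olfr164 (-3.71 ± 0.32), Vasn (-3.42 ± 0.26), Ttll3 (-3.34 ± 0.36), Tlr11 (-3.53 ± 0.37) and the long noncoding RNAs Firre (-3.55 ± 0.39) and Malat1 (-3.47 ± 0.54).

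The pDC markers did not move as a group in KO pDC, with 10 of 24 fallen and 6 risen (list alone 10 and 6; camera adjusted p = 0.74). Klk1 (1.06 ± 0.08), Cox6a2 (1.00 ± 0.08) and Ly6c2 (0.96 ± 0.07) rose, and Ptprs fell from 720 to 352 CPM (-1.04 ± 0.09). Of the identity genes chosen from the het libraries, 302 of 767 pDC-high genes fell and 161 rose (list alone 302 and 162; adjusted p = 0.0158, and 0.244 with an estimated correlation). Of 1341 cDC-high genes 390 rose and 228 fell (list alone 372 and 216; adjusted p = 0.0424, and 0.486 with an estimated correlation). Cadm1 (GeneID 54725, chromosome 9, 47530170 to 47862280), an adhesion gene of cDC1, rose from 64.1 to 489 CPM (2.93 ± 0.15, adjusted p = 1.16e-07), while Clec9a (-0.76 ± 0.06) and Snx22 (-3.08 ± 0.43) fell. The cDC1 list had 9 of 19 genes fallen and 6 risen (list alone 9 and 6; adjusted p = 0.307). The cDC2 list had 7 of 20 genes risen, including Itgam (2.19 ± 0.09), Lyz2 (1.41 ± 0.08) and S100a4 (1.38 ± 0.09), and 6 fallen, including Cd4 at -1.64 ± 0.11 (list alone 7 and 6; adjusted p = 0.0597). Genes shared by the cDC subsets fell in 14 of 20 cases and rose in 3 (list alone 14 and 3; adjusted p = 0.00479, and 0.357 with an estimated correlation).

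MHC class II presentation genes rose in KO pDC in 11 of 15 cases and fell in 2 (list alone 11 and 2; adjusted p = 0.00228, and 0.38 with an estimated correlation). H2-Aa rose by 0.76 ± 0.06, H2-Ab1 by 0.76 ± 0.07, Lgmn by 0.91 ± 0.08 and H2-Eb1 by 0.69 ± 0.06, the last from 2013 to 3255 CPM. Fc and inhibitory receptor genes rose in 11 of 18 cases and fell in 3 (list alone 11 and 3; adjusted p = 0.00123, and 0.357 with an estimated correlation). Fcgr4 was at 2.94 ± 0.15, Fcgr1 at 2.57 ± 0.19, Cd300ld at 2.01 ± 0.13 and Fcgr2b at 1.13 ± 0.08. The textbook PU.1 targets rose in 16 of 32 cases and fell in 8 (list alone 16 and 8; adjusted p = 0.00547, and 0.357 with an estimated correlation). Monocyte markers, which share Itgam, Lyz2 and Fcgr1 with other lists, rose in 15 of 16 (list alone 15; adjusted p = 5.2e-12, and 0.00689 with an estimated correlation), with the chemokine receptor gene Ccr2 going from 328 to 1112 CPM (1.76 ± 0.10) beside Ccr1 at 2.21 ± 0.17. Macrophage markers rose in 15 of 17 (list alone 15; adjusted p = 1.08e-06, and 0.387 with an estimated correlation). Apoe was at 1.70 ± 0.10 and Cd163 at 1.12 ± 0.11. The textbook targets and the monocyte and macrophage markers also rose in het pDC, so their rise against WT was not particular to KO. Against het, textbook targets were higher in KO in 13 of 32 cases and lower in 11 (list alone 13 and 11). Monocyte markers were higher in 10 of 16 and lower in 5 (list alone 10 and 5), and macrophage markers higher in 11 of 17 and lower in 1 (list alone 11 and 1).

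Cell cycle genes rose in 26 of 28 cases in KO pDC (list alone 26; adjusted p = 2.38e-10, and 0.357 with an estimated correlation). Ccnb2 was at 2.77 ± 0.24, Birc5 at 2.60 ± 0.19, Cdk1 at 2.10 ± 0.22 and Mcm5 at 1.07 ± 0.10. Interferon-stimulated genes fell in 11 of 25 cases and rose in 1 (list alone 11 and 1; adjusted p = 0.00745, and 0.689 with an estimated correlation). Among them Mx1 fell by 2.66 ± 0.13, Mx2 by 2.67 ± 0.17 and Stat2 by 0.90 ± 0.06. Irf7, the regulator of interferon production in pDC, fell from 710 to 283 CPM (-1.33 ± 0.19). The list and Irf7 also fell in het pDC, and against het 4 of 25 genes were lower and 2 higher in KO (list alone 4 and 2). The fall of the list was therefore not particular to KO. DC transcription factors fell in 19 of 31 cases and rose in 5 (list alone 19 and 5; adjusted p = 0.0188, and 0.303 with an estimated correlation), including Relb (-1.10 ± 0.08), Bcl6 (-0.84 ± 0.09), Ikzf3 (-1.35 ± 0.10) and Cbfa2t3 (-0.64 ± 0.07). Immediate-early and dissociation genes, which also respond to tissue handling, fell in 15 of 23 cases (list alone 15; adjusted p = 1.51e-10, and 0.121 with an estimated correlation), Nfkbiz by 2.43 ± 0.09 and Dusp1 by 2.02 ± 0.12. Red cell genes rose in 6 of 8 cases (list alone 7; adjusted p = 0.0125, and 0.522 with an estimated correlation). They also rose in het pDC, and none of the 8 was called between KO and het pDC. Neutrophil granule genes (6 of 14 risen; list alone 6; adjusted p = 0.0733), NK cell markers (5 of 17 risen, 2 fallen; list alone 3 and 2; adjusted p = 0.27) and T cell markers (4 of 17 risen, 2 fallen; list alone 3 and 2; adjusted p = 0.802) were not called as groups.

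The effect of the knockout in cDC was tested against that in pDC, where a positive difference means a higher KO effect in cDC. It differed in 4749 genes, 2206 higher and 2543 lower. The KO effect on pDC markers was higher in cDC in 18 of 24 cases and lower in none (list alone 18), by 4.25 ± 0.13 for Ly6d, 3.24 ± 0.11 for Ly6c2, 2.63 ± 0.09 for Sell and 2.27 ± 0.09 for Runx2. Tcf4 (1.13 ± 0.09) and Spib (1.11 ± 0.09) differed in the same direction, and Irf8 (-0.33 ± 0.08) and Flt3 (-0.43 ± 0.08) in the opposite direction. MHC class II genes differed in 14 of 15 cases, all lower in cDC (list alone 14), with H2-Aa at -1.07 ± 0.09, H2-Ab1 at -1.12 ± 0.09, H2-Eb1 at -1.16 ± 0.08 and Marchf1 at -1.48 ± 0.10. The cDC1 list had 11 of 19 genes lower (list alone 12 lower, 1 higher), including Naaa (-2.30 ± 0.10), Ppt1 (-1.76 ± 0.10), Btla (-1.66 ± 0.11) and Clec9a (-0.93 ± 0.08). The cDC2 list had 12 of 20 lower and 2 higher (list alone 12 and 2), with Cd4 at -2.89 ± 0.17 and Itgam at -2.24 ± 0.12, and the textbook PU.1 targets 18 of 32 lower and 1 higher (list alone 19 and 1). Sdc1 rose in KO cDC and fell in KO pDC, a difference of 7.41 ± 0.33. No difference was called for Spi1 itself (-0.13 ± 0.11, adjusted p = 0.365) or for Zfp366 (-0.83 ± 0.46, adjusted p = 0.187).

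Across the 13600 genes the KO effects of the cell types correlated with Pearson's r of 0.534 and Spearman's rho of 0.542. Pearson's r was 0.342 without a filter and 0.442 to 0.521 with a library left out. Genes that rose in both numbered 2486, against 1252.6 if the calls were independent, and genes that fell in both 2358, against 1191.1. At 2-fold or more, 494 rose in both against 92.5, and 469 fell in both against 114.9. Genes of opposite sign were fewer than independence gives, with 309 risen in cDC and fallen in pDC (1182.5) and 438 the other way (1261.7).

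**Figure D3:**
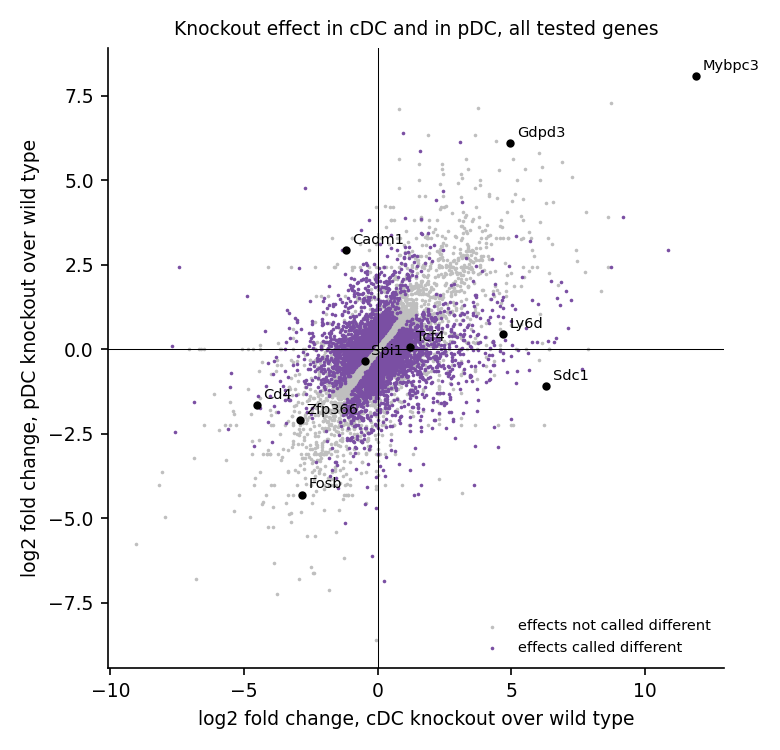
Log2 fold change of KO against WT in cDC (horizontal) and in pDC (vertical) for the 13600 tested genes, with the 4749 genes whose effects differed in purple. Mybpc3 lies at 11.92 and 8.09, Ly6d at 4.71 in cDC, and Cadm1 at 2.93 in pDC.

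KO folds fell with gene length in both cell types. Spearman's rho between log2 fold change and gene length was -0.298 in cDC and -0.305 in pDC, against -0.003 and 0.165 for het against WT. In KO cDC the median was 0.309 for the shortest 25% of genes (up to 1664 bases) and -0.300 for the longest (from 4159 bases), and in KO pDC 0.338 and -0.271. With offsets that take each library's length trend out, 7725 genes were called in cDC, 6464 of them also called with the same sign before, and 7308 in pDC, 6127 of them shared. Under these offsets Clec9a, Ly6d and the other genes named above as KO changes kept their sign and call, except Flt3 and Id2 in pDC. Tcf4, which had not been called in KO pDC, was called with a rise of 0.45, and Csf1r in KO cDC with a rise of 0.90. The cDC1 list stayed at 18 of 19 fallen in cDC and the cell cycle list reached 27 of 28 risen in each cell type, whereas the MHC class II list (adjusted p = 0.0981) and the DC transcription factor list (adjusted p = 0.179) lost their call in KO pDC. The textbook PU.1 targets gained a camera call in KO cDC, with 14 of 32 fallen and 8 risen (adjusted p = 0.0227). In KO pDC the cDC2 list gained a call upward (adjusted p = 0.0484) and the co-stimulation list downward (adjusted p = 0.0336).

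**Figure D4:**
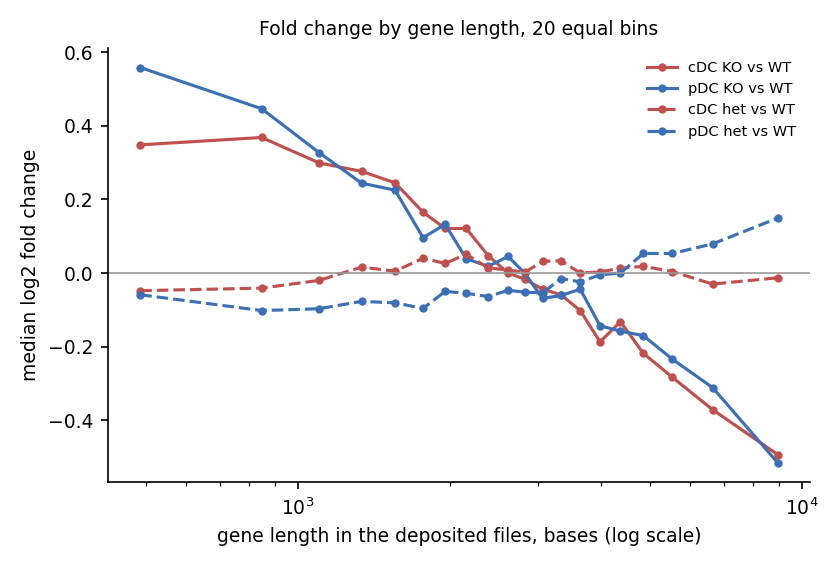
Median log2 fold change (vertical) in 20 bins of gene length (horizontal, bases, log axis) for KO against WT (solid) and het against WT (dashed) in cDC and pDC. The KO lines fall from short to long genes, with medians in the shortest and longest 25% of 0.309 and -0.300 in cDC, while the het line in cDC stays near 0.

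Het cDC were compared with WT cDC. The labels give no day of sorting or preparation, so the comparison does not separate loss of a Spi1 copy from the handling of the cells. The model called 5065 genes, 2639 risen and 2426 fallen, and 1043 rose but only 242 fell by 2-fold or more. The share of risen genes among those called, 52.1%, was 44.2% with length offsets and 44.4% without a filter. The group with the smallest camera p was that of immediate-early and dissociation genes, which respond within minutes to stimulation and to tissue handling, with 22 of 23 risen (list alone 22; adjusted p = 3.52e-101, and 0.000338 with an estimated correlation). Its median log2 fold change was 2.316, below the 6.905 of the neutrophil granule genes. Fos (GeneID 14281, chromosome 12, 85473890 to 85477274) went from 363 to 4769 CPM (3.71 ± 0.08), Atf3 rose by 4.54 ± 0.09, Egr3 by 3.83 ± 0.13 and Dusp1 by 3.04 ± 0.07. Genes of neutrophils, monocytes, NK cells and T cells came next by camera p. All 14 neutrophil granule genes rose (list alone 14; adjusted p = 7.01e-40, and 0.00143 with an estimated correlation), S100a9 from 0.4 to 128 CPM, Ngp by 7.98 ± 0.30, S100a8 by 7.66 ± 0.41, Ltf by 6.07 ± 0.31, Camp 557-fold (99.5 to 22030) and Mpo 149-fold (50.6 to 725). Monocyte markers rose in 9 of 16 cases and fell in 2 (list alone 9 and 4; adjusted p = 9.24e-21, and 0.000796 with an estimated correlation). Chil3 was at 6.45 ± 0.27, F13a1 at 5.69 ± 0.18, Fn1 at 4.41 ± 0.11 and Ly6c2 at 2.53 ± 0.09. NK cell markers rose in 14 of 17 and fell in 1 (list alone 14 and 1; adjusted p = 7.01e-25, and 0.00486 with an estimated correlation). T cell markers rose in 16 of 17 (list alone 16; adjusted p = 7e-16, and 0.00648 with an estimated correlation). Ncr1 was at 3.77 ± 0.16, Prf1 at 3.39 ± 0.19, Zap70 at 3.06 ± 0.27 and Itk at 2.96 ± 0.24. Ctla4 rose by 7.83 ± 0.31 and the innate lymphoid genes in 7 of 10 cases (list alone 7; adjusted p = 7.77e-05, and 0.0201 with an estimated correlation).

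The cDC genes of het cDC split by subset. The cDC1 markers rose in 14 of 19 cases and fell in 1 (list alone 14 and 1; adjusted p = 1.95e-05, and 0.284 with an estimated correlation). Snx22 was at 1.26 ± 0.10, Clec9a at 0.83 ± 0.06, Ppt1 at 0.75 ± 0.07 and Irf8, their regulator, at 0.60 ± 0.06 (adjusted p = 4.62e-07). The cDC2 markers fell in 12 of 20 and rose in 4 (list alone 12 and 4; adjusted p = 1.34e-05, and 0.0204 with an estimated correlation). Cd4 went from 375 to 63.0 CPM (-2.58 ± 0.12), Cd209a at -1.75 ± 0.10, Sirpa at -0.94 ± 0.05 and Notch2, which cDC2 need, at -0.91 ± 0.06. The largest falls were those of Oas1g (-3.53 ± 0.44), Cd209b (-3.15 ± 0.28), Cd207 (-3.05 ± 0.28), Dlgap3 (-3.05 ± 0.35) and H2-M2 (-2.73 ± 0.17). Zfp366 fell by 0.48 ± 0.11 (adjusted p = 0.00434), Spib by 0.46 ± 0.06 (adjusted p = 2.61e-05), Itgax by 0.77 ± 0.06 and Relb by 0.63 ± 0.07. Among regulators Egr2 (4.93 ± 0.22), Nfil3 (3.85 ± 0.12) and Cebpb (1.65 ± 0.13) rose, and Batf3, Id2, Flt3, Tcf4 and Csf1r were not called. The fall of Irf4 (-0.39 ± 0.13, adjusted p = 0.0302) was lost without any 1 of the 6 cDC libraries, at -0.42 to -0.39.

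In het cDC, pDC markers were split at 6 risen and 5 fallen of 24 (list alone 6 and 6; adjusted p = 0.628). Chemokine receptor genes rose in 11 of 20 cases (list alone 12; adjusted p = 8.84e-05, and 0.0201 with an estimated correlation). Cxcr4 was at 2.39 ± 0.08, Sell at 1.09 ± 0.07 and Ccr2 at 0.69 ± 0.10. Interferon-stimulated genes fell in 15 of 25 and rose in 2 (list alone 18 and 2; adjusted p = 4.98e-05, and 0.516 with an estimated correlation). Ifit3 was at -1.94 ± 0.19, Rtp4 at -1.63 ± 0.12 and Mx1 at 0.70 ± 0.12. MHC class II genes fell in 9 of 15 and rose in 1 (list alone 10 and 1; adjusted p = 0.0207, and 0.487 with an estimated correlation). Ifi30 was at -0.65 ± 0.07 and H2-Aa at -0.42 ± 0.06. Cell cycle genes were not called as a group, with 10 of 28 fallen and 2 risen (list alone 11 and 2; adjusted p = 0.0566). The textbook PU.1 targets rose in 13 of 32 and fell in 11 (list alone 13 and 11; adjusted p = 0.0203, and 0.28 with an estimated correlation).

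Het pDC differed from WT pDC in 3278 genes, of which 1828 rose and 1450 fell, and 858 rose but 136 fell by 2-fold or more. The count was 2053 without pDC het replicate 1 and 1513 when only the compared groups were fitted. The share of risen genes among those called was 55.8% and depended on the method, being 43.0% with length offsets, 61.3% with RLE size factors, 67.3% with the DESeq2 Wald test and 70.4% when only the compared groups were fitted. Immediate-early genes rose in 21 of 23 cases (list alone 21; adjusted p = 1.44e-106, and 0.00028 with an estimated correlation). Atf3 was at 4.89 ± 0.14, Dusp1 at 3.69 ± 0.08, Fos from 277 to 2914 CPM and Klf6 at 1.91 ± 0.07. The nuclear receptor genes Nr4a2 (7.48 ± 0.40) and Nr4a1 (4.28 ± 0.13) rose too. All 14 neutrophil granule genes rose (list alone 14; adjusted p = 5.41e-47, and 0.0012 with an estimated correlation). Ngp was at 6.23 ± 0.29, S100a9 at 5.99 ± 0.26, Camp at 290-fold (51.6 to 11470) and Mpo, which had no count in WT pDC, at least 112-fold. Areg rose at least 60.2-fold and Thbs1 163-fold (44.8 to 1353). Monocyte markers rose in 13 of 16 (list alone 13, with 2 fallen; adjusted p = 9.41e-43, and 0.000182 with an estimated correlation), including F13a1 (6.25 ± 0.25), Fn1 (5.69 ± 0.15) and Lyz2 (57.9 to 300 CPM). NK cell markers rose in 15 of 17 and fell in 1 (list alone 15 and 1; adjusted p = 1.03e-20, and 0.00445 with an estimated correlation). Ncr1 was at 3.65 ± 0.29, Prf1 at 3.43 ± 0.30 and Nkg7 at 3.11 ± 0.24. Macrophage markers rose in 15 of 17 (list alone 15; adjusted p = 1.43e-07, and 0.279 with an estimated correlation) and T cell markers in 12 of 17 (list alone 13, with 2 fallen; adjusted p = 9.27e-05, and 0.123 with an estimated correlation). MHC class I genes fell in 10 of 17 cases in het pDC and rose in 1 (list alone 12 and 1; adjusted p = 0.00238, and 0.332 with an estimated correlation).

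Among regulators in het pDC, Nfil3 (2.54 ± 0.13), Cebpb (1.53 ± 0.15) and Zeb2 (0.70 ± 0.07) rose and Id3 fell (-1.56 ± 0.17), while Tcf4, Spib, Irf8, Irf4 and Batf3 were not called. The DC transcription factor list had 13 of 31 risen and 3 fallen (list alone 14 and 4; adjusted p = 0.00273, and 0.0599 with an estimated correlation). Csf1r (1.59 ± 0.31, adjusted p = 0.0120) and Zfp366 (0.91 ± 0.22, adjusted p = 0.0110) rose, and neither was called without pDC het replicate 1, at 1.39 and 0.54. Flt3 fell (-0.21 ± 0.06, adjusted p = 0.00953), but was not called without pDC WT replicate 2 (-0.18) or pDC het replicate 1 (-0.16). The pDC markers fell in 9 of 24 and rose in 2 (list alone 9 and 3; adjusted p = 0.0295, and 0.265 with an estimated correlation). Cd209d was at -0.71 ± 0.08 and Atp2a1 at -0.76 ± 0.09. The cDC1 markers rose in 12 of 19 and fell in 2 (list alone 14 and 3; adjusted p = 2.32e-05, and 0.265 with an estimated correlation). Gcsam was at 1.76 ± 0.20, Snx22 at 1.48 ± 0.20, Naaa at 0.81 ± 0.08 and Clec9a at -0.43 ± 0.06. The textbook PU.1 targets rose in 15 of 32 and fell in 6 (list alone 15 and 6; adjusted p = 9.93e-10, and 0.0279 with an estimated correlation). Il1b was at 2.92 ± 0.11 and Itgam at 1.34 ± 0.10. Interferon-stimulated genes fell in 8 of 25 (list alone 10; adjusted p = 2.34e-05, and 0.45 with an estimated correlation). Irf7 was at -1.18 ± 0.19, Mx1 at -0.87 ± 0.11 and Stat2 at -0.58 ± 0.06. The largest falls that held without any 1 library were those of Bst1 (-2.96 ± 0.17), Cgnl1 (-2.41 ± 0.23) and Slc22a12 (-1.75 ± 0.20).

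**Figure D5:**
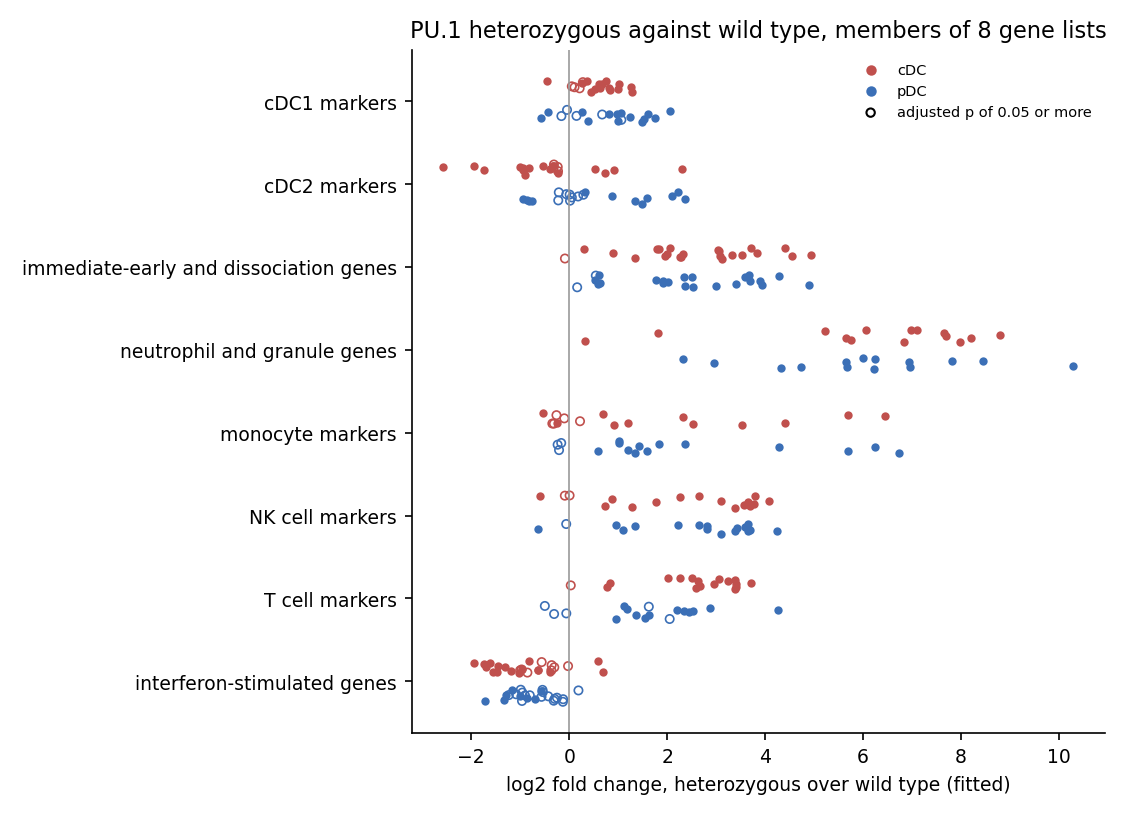
Log2 fold change, het against WT, of each member of 8 gene lists in cDC (red) and pDC (blue), where each dot is a gene and filled dots were called. Immediate-early genes (22 and 21 of 23) and neutrophil granule genes (14 of 14 in each) rose in both cell types.

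The het and KO effects share their WT controls, which alone makes them correlate. In cDC they correlated at r = 0.523 with a covariance of 0.6228, where simulated data without any effect gave r = 0.502 and a covariance of 0.02754. In pDC the values were 0.457 and 0.4521, against 0.487 and 0.02701 in simulation. The observed effects were fitted fold changes, whereas the simulated ones were differences of log2 CPM with a prior count of 2. That prior shrinks genes of low counts, so the observed and simulated values are not like measures and no excess is read from them. In cDC 1121 genes rose in both het and KO (804.3 if independent) and 1281 fell in both (744.7), and 771 rose in het and fell in KO (810.1). In pDC 880 rose in both (552.4) and 752 fell in both (413.7). Part of each excess may come from the shared controls.

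KO and het cells were compared directly, which leaves the WT libraries out of the contrast. The labels give no day of sorting or preparation, so in neither cell type does this separate genotype from the handling of the cells. Immediate-early genes, neutrophil granule genes and cDC1 markers had risen in het cells against WT, which enters their differences from KO. Neutrophil granule genes had risen in KO cDC too, in 10 of 14 cases with 1 fallen. In cDC 8557 genes changed, 4177 higher and 4380 lower in KO, and 1670 were lower by 2-fold or more. All 23 immediate-early genes, all 14 neutrophil granule genes and all 19 cDC1 markers were lower in KO than in het cDC (list alone 23, 14 and 19), among them Clec9a (-2.52 ± 0.06), Snx22 (-3.29 ± 0.11), Ppt1 (-2.20 ± 0.07) and Naaa (-1.98 ± 0.07). The cDC2 markers were higher in 10 of 20 cases and lower in 6 (list alone 10 and 6). Of the regulators Irf8 differed by -1.29 ± 0.06, Zfp366 by -2.43 ± 0.12, Spi1 by -0.71 ± 0.07 and Spib by 2.01 ± 0.07. The pDC markers were higher in 16 of 24 cases and lower in 3 (list alone 16 and 3), the cell cycle genes higher in 25 of 28 and lower in 1 (list alone 25 and 1), and the macrophage markers higher in 14 of 17 (list alone 14). T cell markers were lower in 9 of 17 and higher in 1 (list alone 9 and 1). NK cell markers were lower in 8 of 17 and higher in 4 (list alone 8 and 4). The largest differences were those of Mybpc3 (5.94 ± 0.09), Gdpd3 (5.65 ± 0.13), Ly6k (4.87 ± 0.37), Matn2 (4.49 ± 0.21), Ly6d (4.47 ± 0.11), Nr4a2 (-8.71 ± 0.25) and Ptgs2 (-8.63 ± 0.13), with Efcc1 at least 60.1-fold, Adgrf5 333-fold (91.7 to 2752) and Ccl2 331-fold (59.0 to 13130) lower.

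In pDC 8036 genes differed between KO and het, 4081 higher and 3955 lower in KO. Gdpd3 was higher by 7.07 ± 0.15, Mybpc3 by 6.30 ± 0.10, Plcb1 by 3.43 ± 0.20, Lrrc4c by 3.25 ± 0.26, the pre-T-cell receptor gene Ptcra by 2.98 ± 0.23 and Cadm1 by 2.78 ± 0.15. Fosb (-8.24 ± 0.17), Fos (-6.73 ± 0.10), Tlr11 (-4.59 ± 0.32), Zfp366 (-2.99 ± 0.32) and Spi1 (-0.62 ± 0.08) were lower, as were Ptgs2, 590-fold (106 to 23340), Plk2, 113-fold (38.5 to 552), and Areg, at least 51.0-fold. All 23 immediate-early and all 14 neutrophil granule genes were lower (list alone 23 and 14), as were 13 of 17 NK cell markers, with 2 higher (list alone 13 and 2), and 12 of 17 T cell markers, with 1 higher (list alone 12 and 1). MHC class II genes were higher in 11 of 15 and lower in 1 (list alone 11 and 1), cell cycle genes higher in 25 of 28 and lower in 1 (list alone 25 and 1), and cDC1 markers lower in 14 of 19 and higher in 2 (list alone 14 and 2).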

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

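Each result in this part was picked because the KO effect differed between cDC and pDC in the model, and of the tests of how it held up, the length offsets, the test against a 1.5-fold change and the fit without het libraries were chosen only after the result was seen, while leaving out libraries was planned. The KO effect differed in 4749 of 13600 genes. The difference was set by that single rule, so it names genes that respond unequally and says nothing about why.

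The naming rule picked 5 genes in each direction. The values are fitted differences, first those lower in cDC. Pcdh1 differed by -4.42 (adjusted p = 0.00509), Dmrtb1 by -4.80 (adjusted p = 0.0458), Slc8a2 by -5.13 (adjusted p = 0.0301), Adgrf5 by -5.31 (adjusted p = 0.0179) and Lrr1 by -5.45 (adjusted p = 0.00532). Lrr1 had no count in WT pDC and 19 in KO pDC, so its difference rests on an empty group, and its pDC rise is known only as at least 7.48-fold. The other 4 were expressed in WT cDC and below 0.5 CPM in WT pDC, so their pDC folds rest on few counts. Slc8a2 had 14 counts in WT pDC and 2 in KO pDC, Dmrtb1 4 and 2, and Adgrf5 11 and 3. Slc8a2 lost its call without cDC KO replicate 2 (-4.95) or pDC KO replicate 1 (-1.81), and Adgrf5 without pDC KO replicate 1 (-1.45). Pcdh1 changed sign to 0.131 without pDC KO replicate 1. Of the fits with a library left out, Dmrtb1 kept its call only without a cDC het library or pDC WT replicate 2, and was -4.16 without pDC WT replicate 1. Lrr1 kept its call in every fit.

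In the direction higher in cDC, 5 genes were picked. Gzmc differed by 7.93 (adjusted p = 0.0306), Sdc1 by 7.41 (adjusted p = 3.96e-11), Ptcra by 6.30 (adjusted p = 0.00147), Podnl1 by 5.72 (adjusted p = 0.00033) and Nsg2 by 5.55 (adjusted p = 0.000327). Gzmc and Ptcra had no count in WT cDC, so their differences rest on an empty group, and their cDC rises are known only as at least 155-fold and 35.5-fold. Nsg2 had 1 count in WT cDC. Gzmc lost its call without cDC WT replicate 1 (7.92), cDC WT replicate 2 (7.93), cDC KO replicate 1 (7.91) or pDC WT replicate 2 (5.69). Sdc1, Ptcra, Podnl1 and Nsg2 held in every fit. The KO effects on Sdc1 were 6.31 in KO cDC and -1.09 in KO pDC.

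Of the 10 regulators followed in every comparison, 5 differed. Spib differed by 1.11 (adjusted p = 3.08e-08), Tcf4 by 1.13 (adjusted p = 3.77e-08), Csf1r by -1.37 (adjusted p = 0.0467), Flt3 by -0.43 (adjusted p = 0.00039) and Irf8 by -0.33 (adjusted p = 0.00445). The call of Csf1r was lost when only the compared groups were fitted (-1.37), without the het libraries (-1.37) and without any 1 library other than the 2 of WT pDC, for example pDC KO replicate 1 (-1.33). Those of Spib, Tcf4, Flt3 and Irf8 held without any 1 library. In the test against a 1.5-fold change the calls of Flt3, Irf8, Csf1r, Dmrtb1, Slc8a2, Adgrf5 and Gzmc were lost.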

How the results depend on the processing

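The length offsets, the test against a 1.5-fold change and the fits without het libraries are tests chosen only after the results were seen; the other alternatives were fixed earlier. Over 1004 gene results, 22812 of 23557 refits gave the same call, 683 were weaker, 57 stronger and 5 reversed. Most of these genes were picked for the largest called changes or the smallest adjusted p. Many refits also left out a library outside the comparison, so the share does not describe called genes at large. Over 136 list results, 432 of 532 were the same, 51 weaker, of which 47 with an estimated correlation, 49 stronger, of which 41 with fry, and 0 reversed.

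The test against a 1.5-fold change left 3070 genes in cDC KO against WT and 2324 in pDC, 1009 in cDC het against WT and 722 in pDC, 3061 in cDC KO against het and 2221 in pDC, 5055 between WT pDC and WT cDC, and 1307 for the difference between KO effects.

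Across the alternatives fixed earlier, other than leaving out a library, the counts ran from 7028 to 9285 for cDC KO against WT, 6751 to 8096 for pDC KO, 3779 to 6483 for cDC het, 1513 to 3595 for pDC het and 3764 to 5095 for the difference between KO effects. The low end for pDC het, 1513, came from fitting only the compared groups. Leaving out a library gave 2053 (without pDC het replicate 1) to 3323 for pDC het, 3510 to 5672 for cDC het, 6985 to 8697 for cDC KO, 6943 to 8165 for pDC KO and 3699 to 5010 for the difference between KO effects. Without the het libraries 8222 genes were called in cDC KO, 8100 of them shared, and 7912 in pDC KO, 7784 of them shared.

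The correlation of the KO effects across genes, 0.534, was 0.342 without a filter and 0.442 (without pDC KO replicate 1) to 0.521 with a library left out. The cause of each shift was not tested.

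With length offsets, 88 called genes in cDC KO against WT, 77 in pDC KO against WT, 70 in cDC KO against het and 138 in pDC KO against het were called with the opposite sign. Of the genes that the naming rule picked, 4 turned. Cd7 in pDC KO against WT went to -0.042, Itgb3 in the same comparison to 0.082, Tcf4 in pDC KO against het to 0.462 and Ifnar1 there to 0.163. Without pDC KO replicate 1 the difference between KO effects of Pcdh1 was 0.131, and with the other libraries left out it ran from -5.388 to -4.009.

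The labels do not say whether replicate numbers mark pairs. Deviations of cDC and pDC libraries of the same genotype and number correlated at -0.053 in WT, -0.006 in het and -0.039 in KO, and those of different genotypes within a cell type at -0.102 to 0.248, so no pairing was used. A replicate block gave 8291 genes for cDC KO and 7962 for pDC KO, 5031 and 3237 for het, 8568 and 7998 for KO against het, 9267 between WT cell types and 4331 for the difference between KO effects. In that difference Csf1r (-1.438) and Dmrtb1 (-4.798) were not called with the block.

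With 2 libraries per group and 12745361 to 17665821 counts each, a gene below a few CPM has wide error. The simulation found 88.1% of 1.5-fold changes, all placed in genes with a mean of at least 5 CPM, so it does not cover genes of low counts.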

Other observations

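The gene families here were grouped by tests chosen only after their values were seen. The Ly6 genes rose in KO cDC in 9 of 10 cases, all 9 neighbours on chromosome 15 (camera adjusted p = 1.31e-15, and 0.00344 with an estimated correlation) and in KO pDC in 8 of 10, with 1 fallen (adjusted p = 0.000192, and 0.0392 with an estimated correlation). Ly6a went from 45 to 470 CPM in cDC, Ly6e from 1778 to 3285 and Ly6i from 17.9 to 57.2. With length offsets 9 Ly6 genes rose in KO cDC and 6 in KO pDC (adjusted p = 2.64e-14 and 0.0135). The tissue kallikrein genes rose in KO pDC in 8 of 10 cases (adjusted p = 0.000447, and 0.0796 with an estimated correlation). Both families hold near-identical copies, and the counts do not say how reads that match several copies were placed.

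Ribosomal protein genes rose in KO pDC in 64 of 82 cases and fell in 4 (adjusted p = 4.41e-18, and 0.0392 with an estimated correlation). These genes are short, and with length offsets 44 rose and 10 fell, with the median log2 fold change going from 0.767 to 0.222 (adjusted p = 0.0055). In KO cDC 36 rose and 2 fell without the offsets, whereas 5 rose and 40 fell with them, so no direction is claimed there. They fell in het cDC in 45 of 82 (adjusted p = 8.33e-06, and 0.235 with an estimated correlation). The nuclear RNAs Malat1 and Neat1 fell in KO cells, Malat1 from 230 to 47.8 CPM in cDC and from 405 to 36.6 in pDC, and Neat1 from 59.1 to 22.2 and from 153 to 23.9. Malat1 stood at 66.49 CPM in cDC KO replicate 1 and 29.15 in replicate 2. Hox genes fell in 6 of 10 cases in each KO cell type, with Hoxa5 at -1.57 in cDC and -1.68 in pDC (list adjusted p = 0.302 in cDC and 0.0433 in pDC, the latter 0.258 with an estimated correlation). All 3 haemoglobin genes rose in het and KO cells of both types, Hba-a2 from 2.45 to 17.5 and 23.1 CPM in cDC. Ly49 genes rose in het cDC in 11 of 12 cases (adjusted p = 9.19e-14, and 0.00859 with an estimated correlation).

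Mybpc3 rose to 2845 CPM in KO cDC and 681 in KO pDC. An equal contribution of each inactivated Spi1 copy, run-through from each copy included, would put het libraries at 50% of the KO rise above WT. That holds only if het cells deleted their floxed copy as fully as KO cells did, which was not measured. Het libraries held 1.599% of the rise in cDC and 0.919% in pDC, which argues against an equal contribution only under that condition. Opening of the whole neighbourhood of Spi1 is argued against, because 1 of 21 genes within 500 kb, Nr1h3, rose 2-fold or more in both cell types. Run-through transcription from the Spi1 locus, from each copy or only on the loss of both, and an effect of PU.1 loss on Mybpc3 itself cannot be told apart here. The cDC to pDC ratio of Mybpc3 in KO, 4.175 (3.756 to 4.641), overlapped that of Spi1, 4.341 (3.889 to 4.846), but Mybpc3 stood 2.247-fold above Spi1 per base in KO cDC, and counts per gene hold no reads across the 2354 bases between the genes.

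KO folds fell with gene length, and 4 of 4 KO libraries had a lower slope of log2 CPM on length (-0.181 to -0.169 per doubling) than every other library (0.056 to 0.136). The gene length trend as the whole cause of the KO calls is argued against, because 77.7% of the cDC calls kept their sign under length offsets, and 2056 genes still rose in both cell types against 1025.7 if independent. A difference in RNA or library preparation between genotypes and an effect of PU.1 loss on long genes cannot be told apart here, since all KO libraries share a genotype. Libraries of all genotypes prepared together would separate them.

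In KO cDC, cDC genes fell and pDC genes rose. The presence of pDC like those sorted here in the cDC gate is argued against as the sole source, because the 17 abundant pDC markers other than Siglech, which the Siglec-H- gate sets, would need shares of pDC RNA that differ 59.13-fold among those risen, from 0.306% for Klk1 to 18.1% for Sell, with Ly6d at 5.03%. A shift between cDC1 and cDC2 as the whole cause would lower the markers of 1 subset and raise those of the other. It is argued against because 18 of 19 cDC1 markers and 10 of 20 cDC2 markers fell against WT. The medians were -1.606 and -0.412, but 7 cDC2 markers rose. Of 20 genes listed as shared by both, 18 fell and none rose. That list cannot decide this, because it holds Spi1 and the cDC1 marker Batf3, and its evenness between subsets was not tested. Against het, 10 cDC2 markers were higher and 6 lower while all 19 cDC1 markers were lower, so a shift as part of the cause stays open. Loss of cDC identity in each cell, cells with a partial pDC program and admixture of other cell types stay open, which single-cell counts would resolve. NK1.1+ and CD19+ cells were gated out of both types, so NK and B cell markers do not measure how far other cells entered the gate.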
